A study of Drosophila melanogaster with 6 samples.

How the data were processed

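The deposited files, 1 per library, list each distinct sequence of 18 to 29 nt with 1 annotation name and a signal value, which per the labels is a scaled read count from an Illumina GAII run. Reads were matched by the authors to build dm3, per the submitters' processing notes, and the aligner is not given in the sources used here. Every value was a whole multiple of a fixed step of its library, to within 0.02 reads for values below 200 reads, so whole read counts were recovered by dividing by that step. The white libraries sum to 1000000 and the others carry a further factor (0.573 in nos_shu, 0.875 in nos_piwi, 0.874 in tj_shu, 1.06 in tj_piwi) whose basis is not stated, and which the recovered counts leave out. Reads carry no molecular barcode, so copies made in amplification could not be removed.

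The annotation names of the authors were used as given, since no genome sequence was at hand. They carry no strand and no position. Sense and antisense reads of a family or gene were therefore counted together, reads in single piRNA clusters (flamenco, 42AB, 38C, 20A and 80F) were not analysed here, and reads with several genomic matches could not be told from unique ones. The scale was the number of reads with a miRNA name. piRNA-sized reads were those of 23 to 29 nt, and the piRNA level left out miRNAs, structural RNAs, 2S rRNA and reads of the endo-siRNA loci. The siRNA measures used 21 nt, and the trigger siRNAs were 21-nt reads named for w, shu or piwi.

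Ratios of a knockdown to its white library carry exact 95% intervals conditional on the summed counts. Shares carry Clopper-Pearson intervals and single levels Poisson intervals, and list medians carry intervals from 1000 Poisson draws of the counts. Families needed at least 100 reads of 23 to 29 nt in the white library, and miRNAs at least 1000 reads in either library. The size rule asked for at least 2-fold on the miRNA scale and an interval of the ratio without 1. The lists were fixed before the data were examined, as were the 2-fold size, the minimum counts, the scale and the naming rule. The size rule was first written with the intervals of the 2 levels not overlapping, and the interval of their ratio took the place of this after the files were seen. Of the lists, 20 of 26 germline-biased families, 7 of 7 intermediate and 11 of 12 soma-biased families were found under the names of the files. For the miRNA lists, members with at least 100 reads in either library were measured: 3 of 3 follicle-cell and late-ovary miRNAs, 8 of 8 maternal or germline, 19 of 20 broadly expressed, 3 of 3 heterochronic, 1 of 3 gut and tubule (mir-281, a name that covers 2 list members), and of the 2 muscle miRNAs 1 in the nos and 2 in the tj comparisons. A list median was set against 10000 random lists of the same size, drawn from families of similar level. Level here was the summed log2 level of the knockdown and white libraries, so the matching used the compared value itself. Members of the list could also be drawn. The percentiles therefore describe the lists and test nothing.

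The 10-nt overlap share was adapted to the missing strand. Each 23 to 29 nt transposon sequence was paired with sequences of the same family whose first 10 to 20 nt were the reverse complement of its own, and pairs were weighted by reads. Pairs expected by chance were subtracted, from the pairs found between families. The share is the weight at 10 nt over the weight at 10 to 20 nt, since shorter matches arise by chance without positions, while the design had named overlaps of 1 to 20 nt. On simulated reads of 30 families with known positions the estimate was 9.18% for 9.12%, 33.0% for 32.9% and 42.3% for 42.3%.

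The naming rule, fixed in advance, took the 6 lowest and 6 highest families of the lists, the 5 lowest and 5 highest of all families with at least 1000 reads in the white library, the 4 lowest and 4 highest miRNAs, and the 5 genes with most exonic 23 to 29 nt reads in the white library of each driver. The rule for genes asked for sense and uniquely matching reads, which the files do not separate. Other families and miRNAs named in the text were chosen after their values were seen.

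The calling was tested on simulated counts for all names with at least 100 reads of 23 to 29 nt in the white library, 1259 in each nos comparison and 855 in each tj comparison. Of the 1059 and 655 names set to no difference, none was called in any of the 4 comparisons. At a true ratio of 1.5-fold, 1 of 50 was called in nos_piwi and none of 50 in the other 3 comparisons. At 2.5-fold, 49 of 50 were called in nos_shu and 50 of 50 in each of the others. At 4-fold and at 8-fold, 50 of 50 were called in all 4. The draws held counting error only, so they do not speak for the spread between flies or preparations.

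Alternatives tried were 2 other scales (all listed reads, and 21-nt reads of esi-1 and esi-2), miRNA reads without the 3 most abundant miRNAs, piRNA lengths of 24 to 28 nt, siRNA lengths of 20 to 22 nt, at least 1000 reads per family, at least 100 reads per miRNA, each distinct sequence counted once, and a denominator without structural RNAs. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.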

Results

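Small RNAs from fly ovaries (Drosophila melanogaster) were sequenced in 6 libraries, 1 per group. A double-stranded RNA against white, shu or piwi was expressed from a UAS transgene under nos-GAL4, a driver of the female germ line, or under tj-GAL4, a driver of the somatic follicle cells that surround it. The gene shu encodes Shutdown, an immunophilin-like protein, and piwi encodes the nuclear Argonaute protein that binds piRNAs in both cell types. The gene white encodes a transporter of eye pigment precursors, and its knockdown served as the control of each driver. The series asks whether Shutdown takes part in piRNA production. The nos_white library held 18353194 reads, of which 3351866 were miRNA reads. The nos_shu library held 12974363 reads with 5542860 of miRNAs, and the nos_piwi library 10734568 with 2672638. In the soma-driven libraries the totals were 12572201 for tj_white, 15795742 for tj_shu and 14777060 for tj_piwi, with 1692732, 2652181 and 2516193 miRNA reads.

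Levels are given per 1000000 miRNA reads unless another scale is named, and each knockdown was set against the white library of its driver. With no replicates, no difference could be compared with a spread between samples and no test was made. Intervals are 95% intervals and cover counting error only. A value was called higher or lower by a size rule, which asked for a difference of at least 2-fold and for an interval of the ratio that left out no difference. The shu and piwi comparisons of a driver share the chance values of its white library, and differences between the drivers were not tested.

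The 21-nt siRNAs cut from each hairpin matched the label of every library. Reads of 21 nt named for white reached 8171 per 1000000 miRNA reads (8075 to 8269) in nos_white and 410779 in tj_white. Those named for shu reached 12688 in nos_shu and 67361 in tj_shu, against 2.98 in nos_white and 1.77 in tj_white. Those named for piwi reached 8455 in nos_piwi and 23054 in tj_piwi, against 5.97 and 17.1 in the white libraries. In libraries without the hairpin, the highest values were those of white reads in tj_shu (131) and tj_piwi (304). Each level was higher under tj-GAL4 than under nos-GAL4, by 50.3-fold for white, 5.31-fold for shu and 2.73-fold for piwi. The files hold small RNAs, so the loss of the target mRNAs themselves was not measured.

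**Figure D1:**
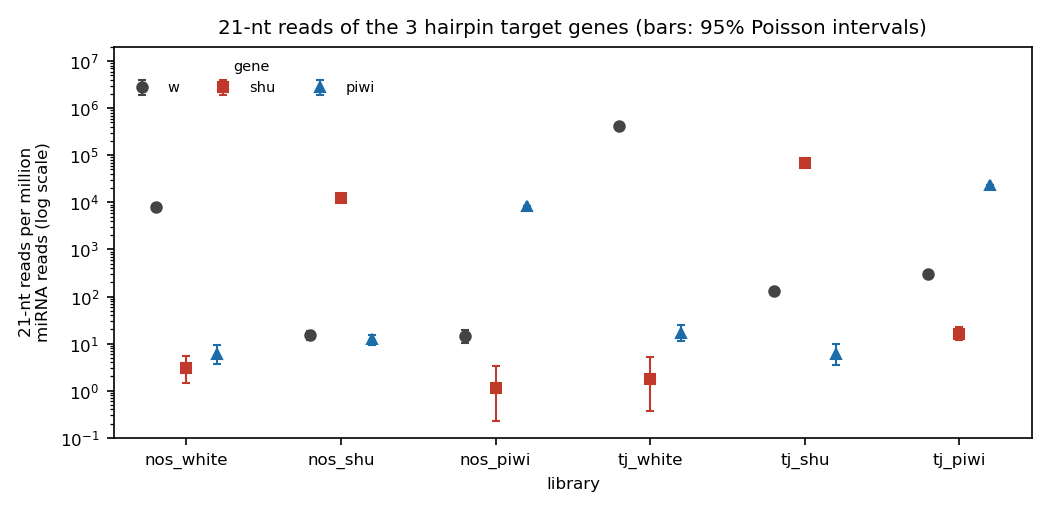
Reads of 21 nt named for white (w), shu and piwi in the 6 libraries, per 1000000 miRNA reads on a log axis; bars are 95% Poisson intervals. In each library the gene of its own hairpin lies highest, from 8171 in nos_white to 410779 in tj_white.

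Germ-line knockdown of shu was accompanied by a low level of piRNA-sized reads. Reads of 23 to 29 nt outside miRNAs, structural RNAs and endo-siRNA loci, which hold the piRNAs, numbered 0.328 per miRNA read in nos_shu and 3.62 in nos_white. Their level lay at 9.07% of the white level (9.05 to 9.08%), a log2 ratio of -3.46, which was lower by the size rule. Reads of 23 to 29 nt made up 38.3% of the nos_shu library and 74.9% of nos_white. The most frequent length of transposon reads was 25 nt in nos_white and 21 nt in nos_shu. Transposon reads of 23 to 29 nt lay at 7.52% of white, reads in introns at 16.5%, reads in exons at 31.7% and unannotated reads at 11.5%. Satellite reads, from simple heterochromatic arrays, lay at 0.535%.

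**Figure D2:**
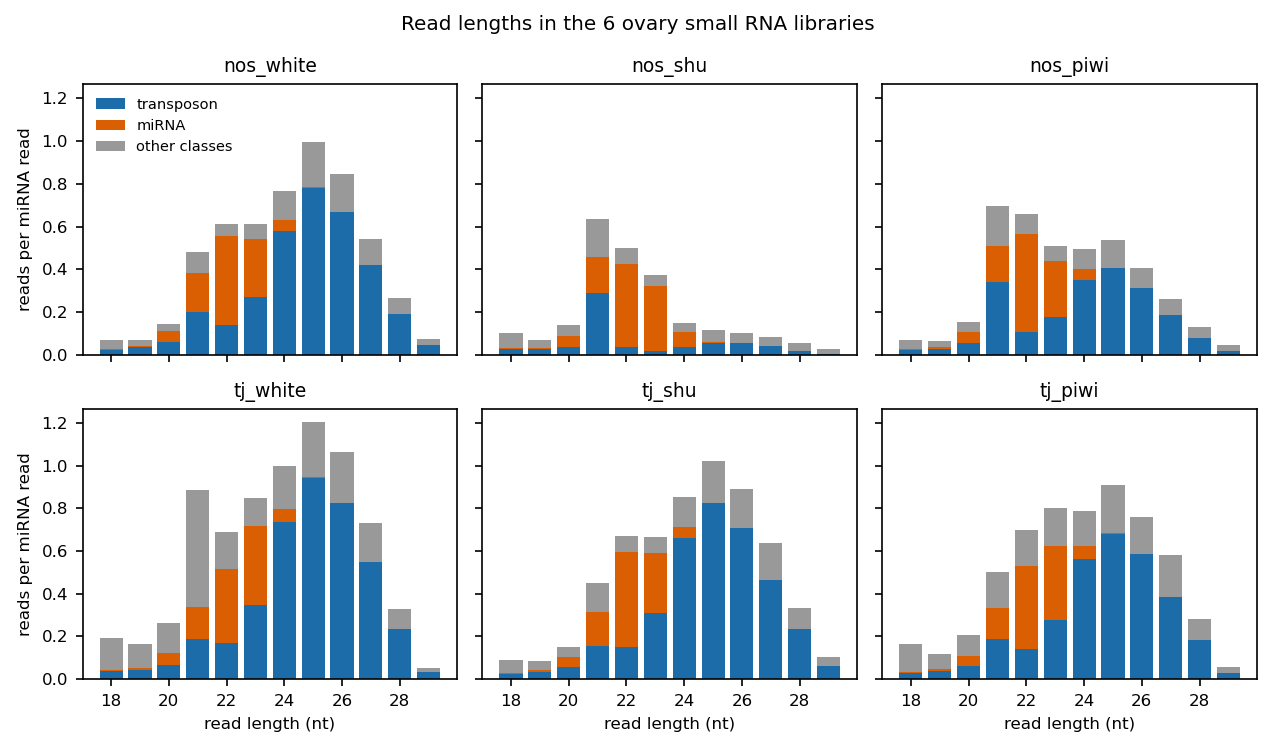
Reads of each length from 18 to 29 nt per miRNA read in the 6 libraries, stacked by class. The peak of transposon reads near 25 nt in nos_white is low in nos_shu, where 23 to 29 nt reads outside miRNAs, structural RNAs and endo-siRNA loci numbered 0.328 per miRNA read.

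Of 130 transposon families with at least 100 reads in nos_white, 123 were lower in nos_shu by the size rule and none was higher, and their median log2 ratio was -5.83, while on the scale of all listed reads 110 were lower and 1, TRANSPAC, was higher. All 20 measured families of the germline-biased list were lower, with a median log2 ratio of -6.49 (-6.54 to -6.44), or 1.11% of white. Among random lists matched on level this median lay at the 3.71 percentile. The lowest were the LINE-type retrotransposons Rt1a (0.125% of white), Rt1b (0.157%), G2 (0.432%) and BS (0.512%), together with TAHRE (0.315%) and HeT-A (0.523%), which maintain fly telomeres. Among all families with at least 1000 reads, BARI (23 reads against 13890), CIRCE (0.217% of white) and R2 (0.244%), an element of the ribosomal DNA, were also among the lowest. Of the 7 families of the intermediate list, 6 were lower, with a median log2 ratio of -1.94. Examples are invader1 at 0.787% of white and copia at 4.89%. On the scale of all listed reads the list median lay within 2-fold, so fewer than 6 families passed there.

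Soma-biased families were retained to a greater extent in nos_shu. Of the 11 measured families, 6 were lower by the size rule and 5 were not, and the list median was -1.17 on the log2 scale (-1.19 to -1.16), at the 100th percentile of random lists, but above 0 on the scale of all listed reads. The highest values of the lists belonged to gypsy10 (77.5% of white), gtwin (65.2%), Tabor (62.0%), ZAM (58.4%), Tirant (55.2%) and gypsy5 (53.7%), all LTR retrotransposons, and on the scale of all listed reads these 6 and gypsy lay above white. Over all families TRANSPAC was highest, at 112% of white, below white on the scale of endo-siRNA reads and higher by the size rule on that of all listed reads. Within the soma-biased list accord lay lowest, at 1.05%. Reads of 23 to 29 nt named for tj (traffic jam), a gene expressed in follicle cells whose 3' UTR is a known piRNA source, lay at 84.3% of white (77.6 to 91.6%) and above white on the scale of all listed reads, at 0.98 on the log2 scale.

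The main genic sources in nos_white differed widely in nos_shu. Reads of RhoGAP18B lay at 41.3% of white, CG32320 at 20.6%, Snoo at 7.45%, CG40813 at 0.416% and CR41608 at 0.213%, and all 5 were lower by the size rule, RhoGAP18B not on the scale of all listed reads. Strand was not given, so sense reads of these genes could not be separated from antisense ones.

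The 10-nt overlap of complementary transposon reads, the mark of reciprocal cleavage by Aubergine and Argonaute3 (ping-pong), was low in nos_shu. Among pairs with 5' overlaps of 10 to 20 nt, 57.8% overlapped by 10 nt in nos_white and 12.9% in nos_shu, where an even spread over the 11 overlaps gives 9.09%. In nos_shu the share was 10.6% over germline-biased families and 35.1% over soma-biased families, against 59.4% and 45.6% in nos_white. Transposon reads without a 5' U carried A at position 10 in 27.7% of cases in nos_shu and 38.7% in nos_white, while the share with a 5' U was 75.1% and 72.1%. The 5' U share was 58.9% in nos_shu and 71.0% in nos_white over germline-biased families, and 81.0% and 77.1% over soma-biased families. The share with A at position 10 was 25.9% and 39.9% over germline-biased families, and 27.3% and 32.5% over soma-biased families. With each distinct sequence counted once, the 10-nt share was 10.9% in nos_shu and 17.3% in nos_white.

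Other small RNA classes did not share the low level of the piRNAs. The 21-nt endo-siRNAs of the structured loci esi-1 and esi-2, which Dicer-2 makes, lay at 158% of white in nos_shu (155 to 161%), and esi-2 alone was 2.05-fold higher, which passed the size rule on the miRNA scale but not on that of esi-1 and esi-2 together. Transposon reads of 21 nt lay at 145% of white, and below white on the scale of endo-siRNA reads. Of 61 miRNAs with at least 1000 reads in either library, 5 made up a higher and 4 a lower share of miRNA reads by the size rule. The largest ratios were 12.6-fold for mir-3, 10.8-fold for mir-314, 3.38-fold for mir-31b and 2.22-fold for mir-980, and mir-10 was the other miRNA with a higher share. The lowest were mir-1012 (46.0% of white), mir-306 (47.0%), mir-284 (48.9%) and mir-9c (49.0%). With at least 100 reads, 9 of 85 miRNAs were higher and 6 lower. The extremes were then mir-309, 28.4-fold higher from 282 and 6 reads, and mir-986, 44.2-fold lower from 32 and 856 reads. The follicle-cell and late-ovary miRNAs mir-989, mir-318 and mir-994 held 26.7% of miRNA reads in nos_shu and 27.6% in nos_white, with none of 3 past the size rule. The 8 maternal or germline miRNAs held 7.99% and 8.18%, again with none past it, and the 3 heterochronic miRNAs 0.560% and 0.956%. Of the broadly expressed list, 2 of 19 were lower (mir-306 and mir-9c), and 17 were within the rule. The muscle miRNA mir-1 lay at 0.488% against 0.377%, and mir-281 of gut and tubule at 0.357% against 0.359%. Fragments of structural RNAs other than 2S rRNA made up 4.95% of the nos_shu library and 1.57% of nos_white, and 2S rRNA 10.8% and 2.99%. Per miRNA read these were 0.116 and 0.0858 for structural RNAs, and 0.252 and 0.164 for 2S rRNA.

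The soma-biased list median in nos_shu turned direction on the scale of all listed reads, where it was 0.06 on the log2 scale. That scale moved all nos_shu ratios by 1.23, and left 121 of the 123 called families below white.

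Germ-line knockdown of piwi went with a smaller difference, spread over most families. The piRNA level lay at 51.1% of white (51.1 to 51.2%), a log2 ratio of -0.97, which missed the 2-fold size rule. Reads of 23 to 29 nt made up 59.2% of the library, and the most frequent transposon length was 25 nt as in nos_white. Satellite reads lay at 28.4% of white and exon reads at 49.1%, both lower by the size rule, exon reads neither on the scale of all listed reads nor without the 3 most abundant miRNAs in the scale, while transposon reads lay at 51.8% and intron reads at 57.6%. Of 130 families, 84 were lower, none was higher, and the median log2 ratio was -1.45.

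Of the 20 germline-biased families, 15 were lower in nos_piwi, and the list median was -1.38 on the log2 scale (-1.40 to -1.37), at the 1.23 percentile of random lists. The median over all families was -1.45, so the list did not lie below families in general. On the scale of all listed reads the list median lay within 2-fold, so fewer than 15 passed there. The telomeric elements stood lowest among the lists, with HeT-A at 6.33% of white, TAHRE at 10.5% and TART-B at 13.9%, followed by BS (16.5%), copia (22.3%) and accord2 (27.2%). Over all families LOOPER1 (8.63%), Invader6 (8.98%), POGO (9.33%) and TART (9.36%) were also among the lowest. Of the intermediate list 2 of 7 were lower, with a median of -0.77, and of the soma-biased list 3 of 11, with a median of -0.60 (-0.62 to -0.59) at the 96.4 percentile. The highest list members were blood (89.1% of white), rover (81.8%), gypsy10 (80.4%), Tabor (77.8%), Tirant (75.3%) and mdg3 (74.8%), and all 6 lay above white on the scale of all listed reads. Several families lay above white without passing the rule: FROGGER (146%), BLASTOPIA (137%), TRANSPAC (131%), G (122%) and Invader2 (120%). On the scale of endo-siRNA reads these 5 families lay below white.

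In nos_piwi the genic sources CG40813 (13.7% of white), Snoo (39.7%), CR41608 (39.8%) and RhoGAP18B (43.1%) were lower by the size rule, the last 3 not on the scale of all listed reads, and CG32320 lay at 78.3%, or above white on the scale of all listed reads. Reads of tj lay at 114% of white (104 to 125%), and below white on the scale of endo-siRNA reads, at -0.38 on the log2 scale. The 10-nt share of overlapping pairs was 57.0%, beside 57.8% in nos_white. It was 54.1% over germline-biased and 36.9% over soma-biased families. A at position 10 was found in 44.3% of transposon reads without a 5' U, and 66.9% of transposon reads had a 5' U.

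The endo-siRNAs of esi-1 and esi-2 lay at 148% of white in nos_piwi and transposon reads of 21 nt at 171%. Of 55 miRNAs, 1 passed the size rule, mir-92b at 2.59-fold, which is also the 1 of 8 maternal or germline miRNAs with a higher share. The next highest were mir-318 (1.67-fold), mir-31b (1.53-fold) and mir-994 (1.45-fold). The lowest were mir-284 (61.0% of white), mir-306 (65.4%), mir-996 (69.3%) and bantam (69.7%). With at least 100 reads, 4 of 80 miRNAs were higher and 2 lower. The extremes were then mir-314, 16.4-fold higher from 931 and 71 reads, and mir-986, 19.5-fold lower from 35 and 856 reads. The 3 follicle-cell and late-ovary miRNAs held 35.6% of miRNA reads against 27.6%, and the broadly expressed list 48.6% against 55.3%, with none of 3 and none of 19 past the rule. The maternal or germline list held 7.79% against 8.18%, the heterochronic list 0.979% against 0.956%, mir-1 0.345% against 0.377% and mir-281 0.487% against 0.359%. Structural RNA fragments other than 2S rRNA made up 2.54% of the library and 2S rRNA 6.26%, or 0.102 and 0.251 per miRNA read. On the scale of endo-siRNA reads the piRNA ratio was -1.53 and on that of all listed reads -0.52, so the former was past 2-fold and the latter was not. On the scale of all listed reads 65 of the 84 called families stayed past the size rule, and all 84 stayed below white.

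**Figure D3:**
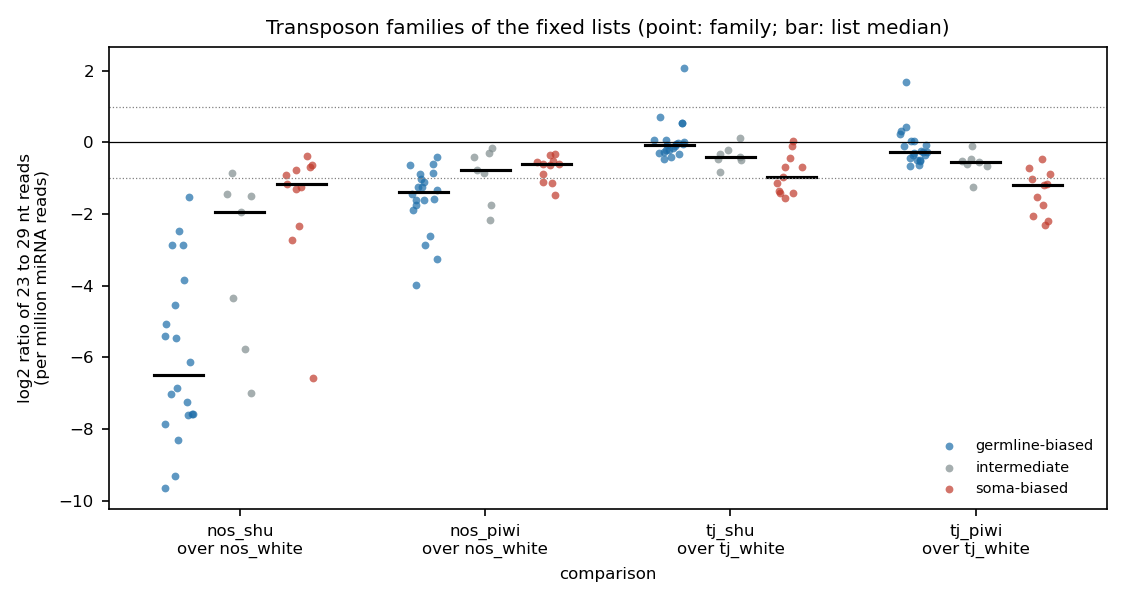
Log2 ratios of 23 to 29 nt reads (knockdown over white, per 1000000 miRNA reads) for the families of the germline-biased, intermediate and soma-biased lists in the 4 comparisons. Points are families, bars list medians, dotted lines 2-fold; the germline-biased median is -6.49 in nos_shu and -0.06 in tj_shu, the latter above 0 on the scale of all listed reads.

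**Figure D4:**
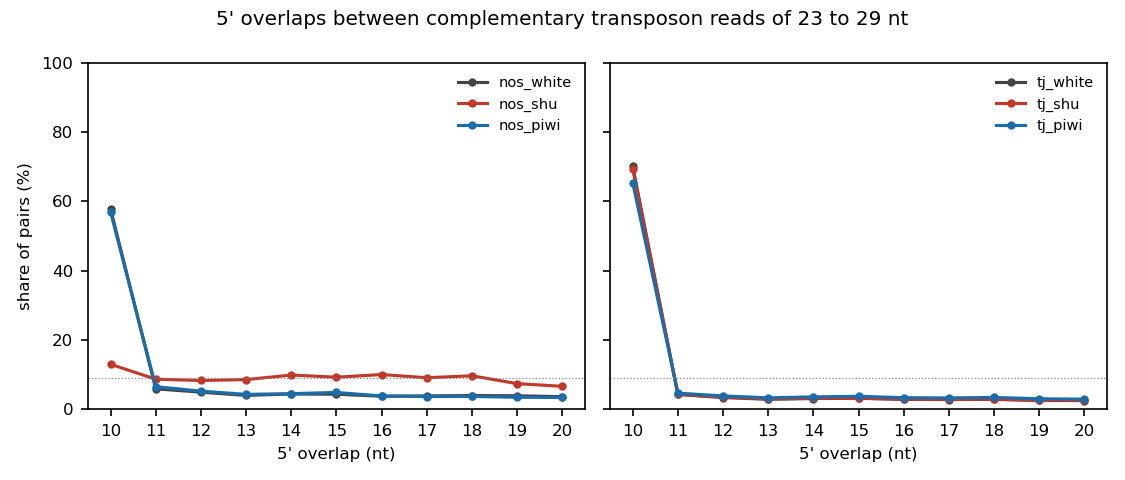
Share of pairs of complementary 23 to 29 nt transposon reads (percent) at each 5' overlap from 10 to 20 nt, with 1 line per library and a dotted line at an even share. The 10-nt share is 12.9% in nos_shu and between 57.0% and 70.2% in the other libraries.

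Follicle-cell knockdown of shu left the bulk of the piRNAs near the white level and went with lower levels of soma-biased families and of tj reads than in tj_white. The piRNA level lay at 89.0% of white (88.9 to 89.1%), and above white on the scale of all listed reads, at 0.15 on the log2 scale. There were 3.89 such reads per miRNA read in tj_shu and 4.37 in tj_white. Reads of 23 to 29 nt made up 75.7% of tj_shu and 70.4% of tj_white, where the white siRNAs take a share of the reads. Reads named for tj lay at 25.9% of white (23.5 to 28.4%), from 615 and 1517 reads, which was lower by the size rule. Their level was 232 in tj_shu and 896 in tj_white, beside 291 in nos_white, 245 in nos_shu and 331 in nos_piwi. The tj_shu level thus lay near those of the nos libraries, and a high level in tj_white cannot be told apart from a low one in tj_shu. Exon reads lay at 74.9% of white and satellite reads at 141%. Transposon reads (89.0%) and unannotated reads (83.2%) lay above white on the scale of all listed reads, and intron reads (102%) below it without the 3 most abundant miRNAs in the scale.

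Of 129 families in tj_shu, 9 were lower and 1 higher by the size rule, with a median log2 ratio of -0.11, and on the scale of all listed reads 4 were lower and 3 higher, with a median of 0.21, and 6 and 12 were lower on the scale of endo-siRNA reads and without the 3 most abundant miRNAs. Of the 11 soma-biased families 5 were lower, and the list median was -0.98 (-1.004 to -0.95), below the medians of all 10000 random lists. The lowest were gtwin (33.9% of white), gypsy5 (37.4%), gypsy10 (37.4%), Stalker2 (39.2%), Tabor (45.9%) and ZAM (50.8%), the last within the rule. DM412, an LTR retrotransposon outside the lists, lay at 40.1%. Of the 7 intermediate families none passed the rule, with a median of -0.42.

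Of the 20 germline-biased families in tj_shu, 1 was higher and 19 were within the rule, and the list median was -0.06 (-0.07 to -0.05), which was above 0 on the scales of all listed reads (0.25) and of endo-siRNA reads (0.05). The telomeric element TART-B was the higher one, at 422% of white. It was followed by Transib3 (162%), mdg3 (146%), roo (146%), rover (109%) and the I-element (105%). Gypsy8 (147%) and DMRT1C (134%) were also among the highest of all families. Without the 3 most abundant miRNAs in the scale, rover and the I-element lay below white.

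Among the genic sources in tj_shu, RhoGAP18B lay at 19.2% of white, CG32000 at 41.98% and CG40813 at 45.6%, all lower by the size rule, the last 2 not on the scale of all listed reads, while Snoo lay at 57.1% and CG32320 at 89.7%, or above white on the scale of all listed reads. The 10-nt share of overlapping pairs was 69.4% in tj_shu and 70.2% in tj_white. It was 71.0% and 72.8% over germline-biased families, and 46.6% and 44.6% over soma-biased families. A at position 10 was found in 40.1% and 40.0% of transposon reads without a 5' U, and a 5' U in 73.1% and 72.8% of transposon reads.

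The endo-siRNAs of esi-1 and esi-2 lay at 92.2% of white in tj_shu, a log2 ratio of -0.12 that was 0.20 on the scale of all listed reads. Transposon reads of 21 nt lay at 81.8%, and above white on that scale. Of 51 miRNAs, 2 passed the size rule, mir-318 at 2.87-fold and mir-994 at 2.46-fold, followed by mir-14 (1.41-fold) and mir-998 (1.38-fold). Both passing miRNAs belong to the follicle-cell and late-ovary list, which held 33.2% of miRNA reads in tj_shu and 22.01% in tj_white, although its member mir-989 made up 10.5% and 13.5%. The lowest of these 51 miRNAs were mir-275 (52.4% of white), mir-34 (55.8%), mir-986 (56.7%) and mir-276 (57.7%). With at least 100 reads, 3 of 73 miRNAs were higher and 4 lower. The lower ones were mir-314 (5.80-fold, from 50 and 185 reads), mir-10 (4.67-fold), mir-252 (2.74-fold) and mir-87 (2.19-fold). The broadly expressed list held 50.1% against 60.1%, the maternal or germline list 8.16% against 8.96% and the heterochronic list 1.06% against 1.13%, with no member of these past the rule. Of the muscle miRNAs, mir-133 was 18.9-fold higher, from 178 and 6 reads, while mir-1 lay at 0.352% against 0.422%, and mir-281 of gut and tubule lay at 0.186% against 0.199%. Structural RNA fragments other than 2S rRNA made up 2.84% of tj_shu and 1.81% of tj_white, and 2S rRNA 4.50% and 9.13%. Per miRNA read these were 0.169 and 0.134 for structural RNAs, and 0.268 and 0.678 for 2S rRNA.

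Follicle-cell knockdown of piwi went with lower levels of the same kinds of reads. The miRNA scale assumes a like cell make-up of the compared ovaries, and a loss of follicle cells was not tested for either tj knockdown. The tj level lay at 3.81% of white (3.03 to 4.74%), from 86 and 1517 reads, or 26.2-fold lower. The piRNA level lay at 73.2% of white (73.1 to 73.3%) (3.197 reads per miRNA read), which was within the size rule. Transposon reads lay at 73.6%, exon reads at 65.3% and unannotated reads at 65.0%, while intron reads (84.7%) and satellite reads (87.0%) lay above white on the scale of all listed reads. Reads of 23 to 29 nt made up 71.2% of the library.

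Of 129 families in tj_piwi, 16 were lower and 1 higher, with a median log2 ratio of -0.44, and 7 were lower on the scale of all listed reads, but 28 on that of endo-siRNA reads and 28 without the 3 most abundant miRNAs. Of the 11 soma-biased families 8 were lower, with a median of -1.18 (-1.20 to -1.16), at the 0.02 percentile of random lists. On the scale of all listed reads this median lay within 2-fold, so fewer than 8 passed there. The lowest list members were gtwin (20.3% of white), Stalker2 (21.8%), gypsy10 (23.99%), gypsy5 (29.5%), Tabor (35.1%) and Tirant (42.4%), with ZAM at 44.3%. Tirant was the 1 of 7 intermediate families that passed the rule, though not on the scale of all listed reads, and the list median was -0.54. DM412 lay at 29.3%. Of the 20 germline-biased families none was lower, 19 were within the rule, and TART-B was higher, at 319% of white. The list median was -0.26 (-0.27 to -0.26), and 0.07 on the scale of all listed reads. After TART-B came Transib3 (135%), roo (124%), mdg3 (118%), invader3 (103%) and HeT-A (102%), of which the last 2 lay below white on the scale of endo-siRNA reads. G5 (120%) and LOOPER1 (117%) were also among the highest of all families.

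Of the genic sources in tj_piwi, RhoGAP18B lay at 10.9% of white, CG32000 at 11.5% and CG40813 at 22.5%, all lower by the size rule, with Snoo at 74.8% and CG32320 at 76.9%. The 10-nt share of overlapping pairs was 65.4%, with 68.4% over germline-biased and 38.9% over soma-biased families. A at position 10 was found in 37.3% of transposon reads without a 5' U, and a 5' U in 74.2% of transposon reads. The endo-siRNAs of esi-1 and esi-2 lay at 114% of white and transposon reads of 21 nt at 101%, and both lay below white without the 3 most abundant miRNAs in the scale.

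Of 58 miRNAs in tj_piwi, 10 made up a higher share by the size rule and none a lower one. The highest were mir-87 (13.0-fold), mir-980 (3.81-fold), mir-9a (2.91-fold) and mir-1 (2.83-fold), and the lowest were mir-989 (53.7% of white), mir-308 (57.8%), mir-986 (61.9%) and mir-283 (62.8%). Both muscle miRNAs were higher, and together they held 1.22% of miRNA reads against 0.423%, with mir-133 at 647 and 6 reads. The follicle-cell and late-ovary list held 21.4% against 22.01%, the maternal or germline list 9.25% against 8.96%, the heterochronic list 1.64% against 1.13% and mir-281 0.223% against 0.199%, with none past the rule. Of the broadly expressed list, mir-9a was the 1 of 19 past it, and the list held 57.7% against 60.1%. Structural RNA fragments other than 2S rRNA made up 6.27% of tj_piwi and 2S rRNA 11.04%, or 0.368 and 0.648 per miRNA read.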

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

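All tests in this part were chosen after the results were seen.

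The shu knockdown differed in direction between the drivers for 3 measures, and these differences were not tested, since each rests on 1 library per group. The endo-siRNAs of esi-1 and esi-2 lay above white in nos_shu and below it in tj_shu, with a difference of the log2 ratios of -0.78. For transposon reads of 21 nt this difference was -0.83. Per listed read both measures lay above white under both drivers. The share of 23 to 29 nt reads lay below white in nos_shu and above it in tj_shu, and the 2 differences from white lay 41.8 percentage points apart. The piwi knockdown showed the same for this share, by 16.4 points, though the tj_piwi share lay below white at 24 to 28 nt and with distinct sequences counted once, and for the tj level, with a difference of the log2 ratios of -4.90, though the nos_piwi tj level lay below white on the scale of endo-siRNA reads. These differences were not tested either. The shares count the siRNAs of the hairpins, which lower the share of 23 to 29 nt reads most in tj_white. There 938765 of 12572201 reads were named for white, 695338 of them of 21 nt. In tj_piwi 74422 of 14777060 reads were named for piwi. With the reads of its own hairpin left out of each library, the tj_piwi share lies below tj_white, and tj_shu lies above it by less.

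Some reads outside the main measurements also lay above the white libraries. Reads of 21 nt named esi-4 were 17.8-fold higher in nos_shu, 16.0-fold in nos_piwi, 5.06-fold in tj_shu and 5.21-fold in tj_piwi. The tj values rest on 222 reads in tj_shu and 217 in tj_piwi, against 28 in tj_white. Differences between the stocks were not tested as a source. Unannotated reads of 21 nt were 2.18-fold higher in nos_shu and 2.74-fold in nos_piwi, both less than 2-fold on the scale of endo-siRNA reads, and lay at 60.1% of white in tj_shu and 53.4% in tj_piwi.

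The low level of 23 to 29 nt reads in nos_shu was weighed against 3 explanations. A size selection against longer RNAs would lower all classes alike, but tj reads of that size lay at 84.3% of white, and above it per listed read. The miRNA scale as the whole cause is argued against by the other scales, on which the piRNA level lay at 21.2% of white at most. A loss of germ-line cells would also lower the 21-nt reads of germline-biased families, if their level per cell were unchanged. Their median level lay at 109% of white (below it on the scale of endo-siRNA reads). But 5 of these 20 families were higher at 21 nt and 2 lower, so a rise per cell could mask a loss of cells. This explanation is left open. With the first 2 explanations argued against, a need for Shutdown in the production of germ-line piRNAs remains a hypothesis from 1 library per group. Off-target effects of the hairpin and differences between the stocks were not tested.

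A set of 148 unannotated 21-nt sequences that part the nos knockdowns from nos_white was weighed next. The set was chosen for a level over 10-fold above nos_white in both nos knockdowns, so the gap to nos_white was fixed by the choice. These sequences summed to 9162 per 1000000 miRNA reads in nos_shu and 8391 in nos_piwi, against 326 in nos_white and 208 in tj_white. Sequence of the hairpin constructs is argued against by tj_shu and tj_piwi, where the same hairpins gave at most 1.77% of the nos level. A strain difference between nos_white and both nos knockdowns may be the source, since 2 of 139 miRNA arms part these libraries by over 10-fold: mir-986-5p, with 805 reads in nos_white and 5 and 3 in the knockdowns, and mir-314-3p. How many arms a strain difference would part is not known, so this count cannot decide. Reads of 21 nt named TRANSPAC and esi-4 also lay above nos_white in both nos knockdowns, though esi-4 reads lay above white in the tj knockdowns too. An effect of the knockdowns cannot be told apart from a strain difference.

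The high level of TART-B reads in tj_shu and tj_piwi was the last pattern. A few abundant sequences do not account for it, since the lower ratio stayed at 3.19-fold without the 10 most abundant sequences of each tj library. Reads shared with the TART family would lower TART, which lay at 97.6% of tj_white or above on the main scale and above it per listed read. Fewer TART-B copies in the tj_white flies could be the source, since nos_white lay 2.57-fold above tj_white, but this is less than both knockdown ratios. Copy number was not measured, so it cannot be told apart from an effect of the knockdowns.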

How the results depend on the processing

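Of 116 values under alternatives to 44 results, 30 stayed within the interval of the main value (a count within 1.5 times of it), 85 moved and 1 reversed, where reversed means that a value past the size of 2-fold changed sign. Values of less than 2-fold that changed sign are counted as moved. They are the piRNA and endo-siRNA ratios of tj_shu, the tj ratios of both nos knockdowns, the germline-biased medians of both tj knockdowns and the piRNA-sized share of tj_piwi. Outside these 116 values, the endo-siRNA ratio of tj_piwi lay below white without the 3 most abundant miRNAs. Values below are log2 ratios to white unless another unit is named, and the cause was not tested. Most moves are small, since the intervals hold counting error only.

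Per 1000000 listed reads, piRNA ratios were -2.24 in nos_shu, -0.52 in nos_piwi, 0.15 in tj_shu and -0.11 in tj_piwi. Those of tj were 0.98, 0.63, -1.63 and -4.37, those of the endo-siRNAs 1.88, 1.01, 0.20 and 0.53, and germline-biased medians -5.26, -0.94, 0.25 and 0.074. Soma-biased medians were 0.055 in nos_shu, the 1 reversal of a value past 2-fold, then -0.15, -0.66 and -0.84. Families lower by the size rule numbered 4 in tj_shu and 7 in tj_piwi. This scale counts the piRNAs themselves, and by its construction every ratio of a comparison moves by the same amount. In the tj comparisons it also counts the hairpin reads. These numbered 938765 for white in tj_white, 231569 for shu in tj_shu and 74422 for piwi in tj_piwi. Their larger number in tj_white raises every tj ratio on this scale.

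Per 1000000 endo-siRNA reads, piRNA ratios were -4.12 in nos_shu, -1.53 in nos_piwi, -0.052 in tj_shu and -0.64 in tj_piwi, germline-biased medians -7.15, -1.95, 0.052 and -0.46, and soma-biased medians -1.83, -1.16, -0.86 and -1.37. Those of tj were -0.91 in nos_shu and -0.38 in nos_piwi, and 28 families were lower in tj_piwi. Without the 3 most abundant miRNAs in the scale, piRNA ratios were -3.32, -0.90, -0.47 and -0.66.

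With piRNAs of 24 to 28 nt, piRNA ratios were -3.47, -1.01, -0.18 and -0.47 in nos_shu, nos_piwi, tj_shu and tj_piwi. Germline-biased medians were -6.69 in nos_shu and -1.45 in nos_piwi, and soma-biased medians -1.12 in nos_shu, -1.05 in tj_shu and -1.27 in tj_piwi. The share of piRNA-sized reads lay at 34.1% of white in nos_shu, 72.9% in nos_piwi, 108% in tj_shu and 97.1% in tj_piwi. It lay at 45.6%, 82.9%, 102% and 96.7% with each distinct sequence counted once, and at 47.7%, 78.2%, 105% and 102% without structural RNA, beside main values of 51.2%, 79.1%, 107% and 101%. The tj_piwi share thus lay on either side of white.

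With at least 1000 reads in white, germline-biased medians were -6.84 in nos_shu, -1.32 in nos_piwi and -0.080 in tj_shu. With siRNAs of 20 to 22 nt, endo-siRNA ratios were 0.58 in nos_shu, 0.83 in nos_piwi and 0.31 in tj_piwi. Trigger siRNAs then reached 9683 per 1000000 miRNA reads in nos_white, 15079 in nos_shu, 10265 in nos_piwi, 520388 in tj_white, 82368 in tj_shu and 27706 in tj_piwi. With distinct sequences counted once, the 10-nt share of overlaps was 17.3% in nos_white, 10.9% in nos_shu, 16.5% in nos_piwi, 20.6% in tj_white, 19.8% in tj_shu and 18.8% in tj_piwi. With at least 100 reads, 15 miRNAs were past the size rule in nos_shu, 6 in nos_piwi, 7 in tj_shu and 16 in tj_piwi.

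One alternative was chosen after seeing the data, the piRNA level without reads named for w, shu or piwi, which was -0.17 in tj_shu and -0.45 in tj_piwi and within the interval in both nos comparisons. The low piRNA level of nos_shu, its low germline-biased median and the low tj level of both tj knockdowns kept their direction under every alternative and stayed past 2-fold. All are ratios to the white library of the same driver, and for tj the tj_white level (896) lay above that of nos_white (291). The soma-biased medians of both tj knockdowns and all medians of nos_piwi kept their direction.

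Not run were the alternatives for flamenco and 42AB, those for multiple matches and the overlap share in 42AB, which need a genome. Sense and antisense reads together, planned as an alternative, became the main measure because strand was not given, and antisense reads alone were not run. No paired analysis was possible because each group held 1 library and the labels name no pairs.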

Other observations

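Reads of 21 nt from some transposon families lay above white in all 4 knockdowns. In nos_shu 20 of 130 measured families were higher than white at 21 nt by the size rule and 10 were lower, and in nos_piwi 32 of 129 were higher and 5 lower. These counts depend on the scale, with 7 higher and 32 lower in nos_shu and 11 and 10 in nos_piwi per endo-siRNA read, and 87 and 1 in nos_shu and 60 and 3 in nos_piwi per listed read. In tj_shu the counts were 4 higher and 13 lower of 129, and in tj_piwi 7 and 26. Per listed read they were 4 and 3 in tj_shu and 9 and 13 in tj_piwi, and per endo-siRNA read 4 and 8, and 6 and 37. Among abundant families, chosen after their values were seen, TRANSPAC was 47.3-fold higher in nos_shu and 34.4-fold in nos_piwi, from 304 reads in nos_white. Baggins1 was 6.74-fold and 6.66-fold higher, HOBO 4.81-fold and 7.07-fold, BEL 6.83-fold and 5.24-fold, mdg3 6.97-fold and 4.35-fold, and BLASTOPIA 3.93-fold and 3.61-fold. For these families, as for the unannotated sequences, a strain difference between nos_white and both nos knockdowns cannot be told apart from an effect of the knockdowns. In tj_shu and tj_piwi 21-nt reads of these families lay between 61.2% and 136% of white, while other families were higher there. Stalker2 was 13.9-fold higher in tj_piwi, DM412 12.8-fold, ZAM 4.30-fold and mdg1 3.399-fold, and in tj_shu DM412 was 5.36-fold, TART-B 2.89-fold, ZAM 2.84-fold and Stalker2 2.45-fold higher. The soma-biased families summed to 134% of white at 21 nt in nos_shu, 185% in nos_piwi, 90.9% in tj_shu and 158% in tj_piwi, but their median log2 ratio was 0.022 in nos_shu, 0.49 in nos_piwi, -0.31 in tj_shu and -0.17 in tj_piwi, so the tj_piwi sum rests on a few families. Each of these 4 medians has the other sign on 1 of the other scales. The germline-biased families summed to 120% in both nos knockdowns, 80.8% in tj_shu and 82.0% in tj_piwi. On the scale of endo-siRNA reads these sums lay below white for nos_shu and for the germline-biased families of nos_piwi. On the scale of all listed reads they lay above it for both lists of tj_shu and the germline-biased families of tj_piwi. The base composition differed as well: 31.8% of 21-nt transposon reads began with U in nos_shu and 36.7% in nos_piwi, against 47.1% in nos_white and between 49.6% and 53.0% in the tj libraries.

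The 2 white libraries were not alike. Of 116 families with at least 1000 reads in nos_white, 5 were higher in tj_white by the size rule: blood (3.62-fold), TART (3.38-fold), BEL (3.11-fold), Stalker2 (2.69-fold) and HELENA_RT (2.61-fold). TART-B was the 1 lower family, and the median log2 ratio of tj_white over nos_white was 0.27.

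Reads of 21 nt named for white were present at 347 reads in tj_shu and 765 in tj_piwi, which is 0.0319% and 0.0740% of the tj_white level. Of these reads, 87.6% and 96.7% had a sequence also found at 21 nt in tj_white.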
